A study of Mus musculus with 12 samples.

How the data were processed

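RNA was measured in leukaemic cells of 4 mice, 2 KI/wt and 2 KD/KD, from TruSeq Stranded mRNA libraries. The counts per gene were deposited by the authors, whose labels name TopHat2 2.0.10, SAMtools, HTSeq and DESeq with the mouse build GRCm38. The strand setting of the counting, the annotation release and any read filter are not given in the sources used here. For stranded libraries the opposite strand setting would leave most reads in no feature, and that setting is not excluded here. The values are raw counts for 41214 Ensembl genes, of which 40254 have a symbol in the annotation used here, and the deposited summary entries that name no gene hold between 93.2% and 97.9% of each library's total and were left out. Gene counts came to 4581593, 10869534, 11934542 and 10263454 for KI replicates 1 and 2 and KD replicates 1 and 2, so that 3 counts correspond to 0.696, 0.356, 0.212 and 0.259 CPM. Reads assigned to no feature were 88.3%, 68.3%, 67.4% and 63.2% of the uniquely aligned reads.

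The 8 chromatin libraries (Bowtie2 2.10, SAMtools and HOMER, build mm10, per the labels) are not analysed here. Their 4 tables hold 4 blocks of 101 bins each, in steps of 25 bp from -1250 to 1250, with 31633 to 32227 entries per table. The 1616 per-sample columns of these tables name neither antibody nor mouse, so none could be matched to a library by name, and they are not used here.

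The counts were analysed in R 4.3.3. Genes were kept by edgeR 4.0.16 filterByExpr with the genotype as group (13822 genes), scaled by TMM (factors 0.957, 0.778, 1.19 and 1.13) and tested with glmQLFit and glmQLFTest, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.204 and the prior degrees of freedom 3.56. Fold changes are log2 of KD over KI with the standard error of the fit, and CPM values are scaled by TMM. The p-values measure only the spread between these 4 mice, and intervals of count ratios cover counting error alone.

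The genotypes, tests, gene lists, alternatives and naming rule were fixed before the data were examined. The rule named Gfi1, the 12 genes with the largest fold change in each direction among genes past the threshold and, where fewer passed, those with the lowest p, given a mean of at least 5 CPM, a symbol that is no predicted gene, and both KD libraries on the same side of both KI libraries. It also named the 3 members of each list with the lowest p. Not every gene the rule picked is printed. The 26 lists held 613 different genes, 515 of them measured. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over the 26 lists, again with an estimated correlation, and with fry. Members were adjusted over all genes tested and over the list alone.

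Alternatives were RLE, upper quartile and library size only scaling, no low-count filter, at least 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fold threshold of 2, and leaving out each library in turn. Each leave-one-out fit reran the filter, so genes could enter through 1 library alone and lists could gain or lose members. List tests in those fits used the preset correlation. Alternatives added after the data were seen were leaving out loci at satellite repeats, lists limited to genes of at least 20 CPM on average, a robust dispersion prior, and leaving out sex-linked genes. The edgeR fit was tested on simulated data with 200 of 13822 genes changed singly and another 25 shifted together as a list. With dispersions on the trend it called 27 of 50 genes changed 4-fold, 45 of 50 changed 8-fold and 49 of 50 changed 16-fold, and 8 of the 13597 genes left without a change. With trended dispersions scattered between genes by the prior degrees of freedom of the quasi-likelihood fit, it called 0 of 50 at each of these sizes and at 32-fold. Whether that scatter matches the true one is not known.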

Results

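Leukaemic cells were taken from C57/BL6 mice that carry the NUP98-HOXD13 transgene, a fusion of a nuclear pore gene with a homeobox gene that drives myelodysplasia and acute myeloid leukaemia in mice. The series compared 2 Gfi1 genotypes, with 2 mice of each: KI/wt, called KI here, and KD/KD, called KD here. Gfi1 encodes a zinc finger repressor that guides blood progenitors towards the granulocyte lineage. RNA was sequenced from 4 libraries, 1 per mouse. Another 8 libraries, 4 of histone H3 and 4 of H3K9ac, an acetylation mark of active promoters, came from chromatin immunoprecipitation and are not analysed here. Counts assigned to genes came to 4581593 in KI replicate 1, 10869534 in KI replicate 2, 11934542 in KD replicate 1 and 10263454 in KD replicate 2. The libraries are stranded, the strand setting of the counting is not stated, and 63.2% to 88.3% of uniquely aligned reads fell in no gene, so whether counts come from the sense strand is open for each value printed here. Loci annotated over satellite-like repeats took 40.5% and 45.8% of the gene counts in the KI libraries, and 20.2% and 21.9% in the KD libraries. Odorant, pheromone and taste receptor genes, which blood cells do not use, summed to 832 CPM (counts scaled to library size) in KI replicate 1 and to between 144 and 166 in the other 3 libraries.

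**Figure D1:**
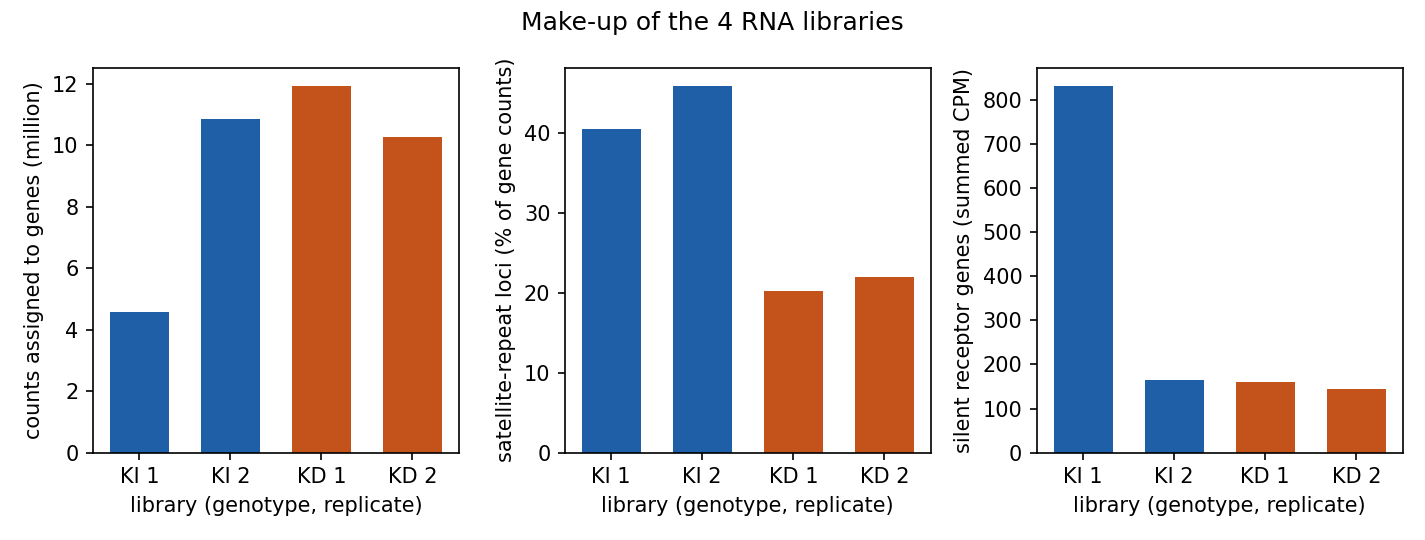
Bars give, for each of the 4 RNA libraries (KI in blue, KD in orange), the counts assigned to genes, the percentage of those counts at 13 satellite-repeat loci, and the summed CPM of silent receptor genes. Both KI libraries hold 40.5% and 45.8% satellite counts against 20.2% and 21.9% in KD, and KI replicate 1 has the lowest total, 4581593, and the highest receptor sum, 832 CPM.

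The first question was whether Gfi1 itself followed the genotype labels. Gfi1 (ENSMUSG00000029275, GRCm38 chromosome 5, 107716655 to 107725805) was lower in both KD libraries than in both KI libraries. Its level was 36.2 and 89.0 CPM in the KI mice, a mean of 62.6 ± 37.3 (SD, n = 2), and 7.22 and 1.12 CPM in the KD mice, a mean of 4.17 ± 4.31 (SD, n = 2). The counts behind these values were 156, 750, 102 and 13. The fitted log2 fold change, KD minus KI, was -3.89 ± 0.95 (SE), a ratio of 14.9, with adjusted p = 0.518 in edgeR's quasi-likelihood test. DESeq2 gave -3.76 with adjusted p = 0.0012. In edgeR the value was -4.22 without KI replicate 1, -2.96 without KI replicate 2, -5.73 without KD replicate 1 and -3.09 without KD replicate 2. Each of these fits leaves a lone mouse in 1 genotype, whose spread is not measured. Mouse lines of these names carry human GFI1 coding sequence in the altered allele, so counts on the mouse gene measure the mouse allele and any shared untranslated parts, not the total dose of GFI1.

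Across the genome, the gene with the lowest p was Hbb-y, an embryonic beta-like globin, lower in KD at 133.8 and 58.5 CPM in KI against 3 counts in the KD libraries together. The KI to KD ratio of its pooled counts was 720 (95% exact binomial interval 246 to 3495, counting error only). Camp, the cathelicidin antimicrobial peptide, had a log2 fold change of -4.03 ± 0.45 (SE), Slfn4, a Schlafen family gene, -3.34 ± 0.45, and Olfm4, a neutrophil granule protein, -3.76 ± 0.58. Others lower in KD were Ttc39b, Svep1, Tanc1, Acpp, Cd9 (a tetraspanin), Itih5, Tmem56 and Syngr1, with log2 fold changes between -4.81 and -2.14. Higher in KD were Scarb1, the receptor for high-density lipoprotein (62.6 ± 1.40 CPM in KI, 149.9 ± 21.4 in KD, SD, n = 2), and Hoxc6, a homeobox gene (6.80 ± 0.55 against 26.1 ± 8.88). The same direction held for Klf4 and Cd14 of the monocyte lineage (log2 1.18 ± 0.29 and 1.46 ± 0.36), and for Nfkb1, the precursor of the p50 subunit of NF-kB (1.04 ± 0.26). Tmem109, Tmem268, Sgms2 (a sphingomyelin synthase), Map3k20 and Lrrc8b were higher by log2 1.14 to 1.51, and Prg2, the eosinophil major basic protein, by 4.29 ± 1.09, with unequal levels of 102.5 and 14.2 CPM in the KD mice. None of these genes passed edgeR's test with Benjamini-Hochberg adjustment: Hbb-y had adjusted p = 0.300, the lowest of the 13822 genes tested, and the others named here adjusted p = 0.518. With the replicate number as a block, edgeR called 7 genes lower in KD, among them Hbb-y (adjusted p = 0.0015), Camp and Slfn4 (both adjusted p = 0.0461), and 0 higher. Replicate number also goes with the levels of sex-linked genes in both genotypes.

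In that test 0 genes were called higher and 0 lower in KD, while 1331 had an unadjusted p under 0.05, 178 of them higher and 1153 lower in KD. On simulated data with scattered dispersions the test called 0 of 50 genes even at 32-fold, so the lack of calls does not show a lack of change. Both KD libraries lay on the same side of both KI libraries for 5253 genes (38.0%, where chance gives 33.3%), 2009 of them higher and 3244 lower in KD. The Pearson correlation across genes was 0.858 between the KI libraries and 0.958 between the KD libraries. Each KI library lay closer to each KD library (0.869 to 0.917) than to the other KI library. DESeq2 called 5 genes higher (Prg2, Hoxc6 and Scarb1, and Ly6e and Txndc5, named after their values were seen) and 137 lower, among them Hbb-y, Camp, Ngp, Slfn4, Olfm4, Ets1 and Gfi1. Limma-voom called 0 in either direction. Of the genes at an unadjusted p under 0.05, 13.4% were higher in KD with TMM factors, 20.4% with RLE and 9.33% with upper quartile scaling. DESeq2 gave 17.6% and limma-voom 26.3%. The balance turned to 77.2% with library size only, which makes no correction for the unequal satellite shares of the genotypes. Leaving out 1 library left a lone mouse assumed to vary like the other genotype. The low-count filter was rerun, so a gene could enter through 1 library alone. Genes tested were 14164 without KI replicate 1, 16755 without KI replicate 2, 16932 without KD replicate 1 and 16983 without KD replicate 2. With all 4 libraries 13822 were tested, so counts of calls cannot be compared between these fits. The genes called higher without a KD library, all but Prg2 named after their values were seen, were few. They were Epha2 and Igkv3-5 without KD replicate 1, and Prg2, Pcdh17, Plcb1, Epx and Stfa1 without KD replicate 2.

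**Figure D2:**
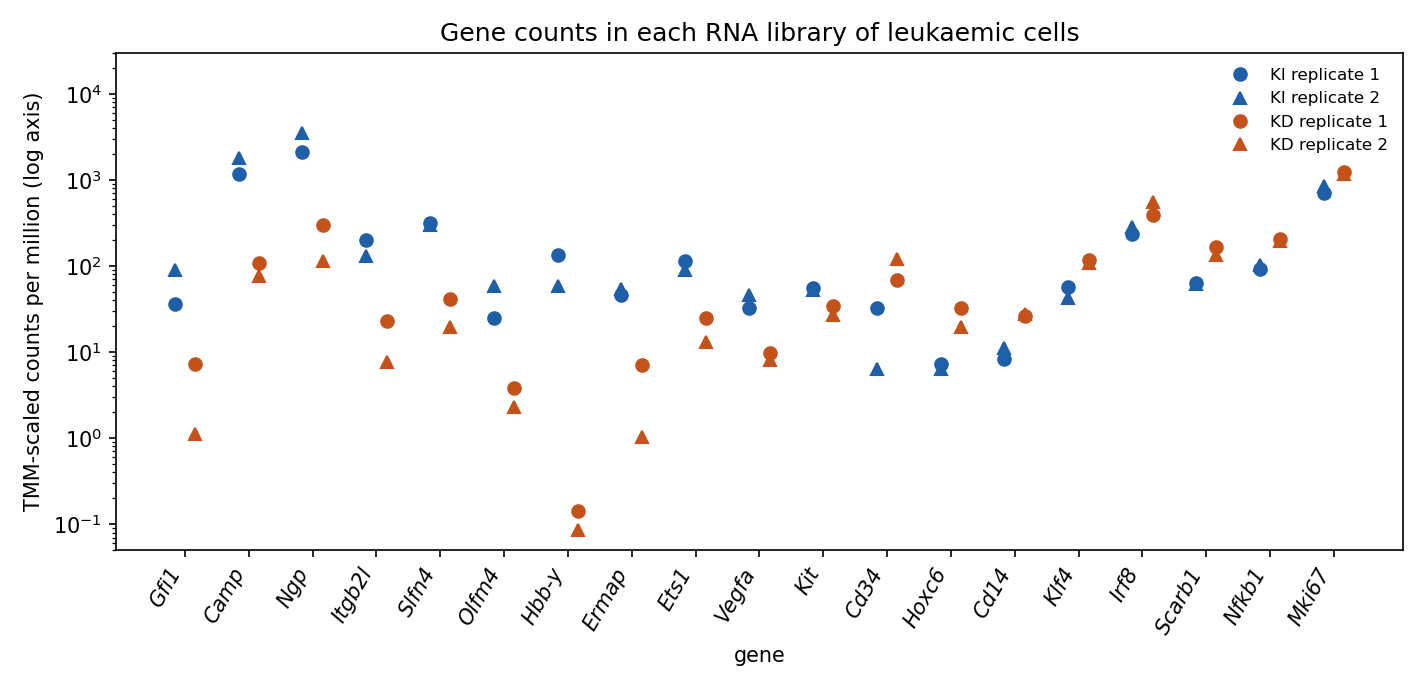
Each point is 1 library: TMM-scaled CPM on a log axis for genes picked by the naming rule, KI in blue, KD in orange, replicate 1 as circles and replicate 2 as triangles. For every gene drawn, both KD points lie on the same side of both KI points; Hbb-y lies at 133.8 and 58.5 CPM in KI and at 0.142 and 0.0864 in KD, and Camp at 1183 and 1806 against 107 and 76.1.

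Genes of late granulocyte maturation were mostly lower in KD, and genes of the earlier primary granule went both ways. The difference between these lists was not tested. Of 26 measured members of the secondary granule and mature neutrophil list, 25 had a negative fold change and 18 lay lower in both KD libraries than in both KI libraries. The median log2 fold change was -1.67. Ngp, the neutrophilic granule protein, lay at 2127 and 3550 CPM in the KI mice and 298 and 116 CPM in the KD mice (log2 -3.78 ± 0.65, SE), and Itgb2l, an integrin subunit of neutrophils, 202 and 130 against 23.2 and 7.78. Lactoferrin (Ltf, -3.41 ± 0.81), S100a9 (-2.81 ± 0.65) and the neutrophil surface gene Ly6g (-4.39 ± 1.06), named after their values were seen, lay the same way, whereas Mmp8, Csf3r, Itgam and Cybb had values between -0.06 and 0.05. The list was lower as a group by camera with a preset correlation of 0.01 (adjusted p = 5.8e-10 over 26 lists), but not otherwise (adjusted p = 0.889 with an estimated correlation). No member passed over all genes tested, and 15 passed, all lower, when adjusted over the list alone. The estimated correlation of the list was 0.321. Without each library in turn the median stayed negative, at -2.34 to -1.35. In the primary granule list, 9 of 18 members were positive and 9 negative, with a median of -0.0084 (adjusted p = 0.634). This list had a mean of -0.23, a test direction of higher in KD and a median of 0.43 with library size only. It was called higher without KI replicate 2 (0.60, adjusted p = 0.0126), but its median was -0.44 without KD replicate 2 and -0.16 without KI replicate 1, and with all 4 libraries it had adjusted p = 0.923 with an estimated correlation. Mpo, Elane and Ctsg, its most familiar members, had values of 0.28 ± 0.54, 0.02 ± 0.48 and 0.02 ± 0.75, whereas Cebpe, a transcription factor needed for secondary granules, had -2.04 ± 0.60, Rgcc -2.18 ± 0.88 and Plac8 0.80 ± 0.29. Without KI replicate 2, Cebpe lay at -0.80 and Rgcc, whose groups overlap, at -0.26.

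Monocyte genes had mostly positive fold changes, and whether the list was called rested on the setting. The monocyte and macrophage list had 20 of 30 measured members positive, a median of 0.60, a mean of 0.04 and adjusted p = 0.104, and 0 members passed over all genes or adjusted over the list alone. Klf4 and Cd14 were its members with the lowest p, and C1qa, a complement gene of tissue macrophages, lay the other way at -3.16 ± 1.09 on fewer than 21 counts per library. The list was called without KI replicate 1 (median 0.98, adjusted p = 0.0045) and without KD replicate 2 (0.66, adjusted p = 0.000214). It was not called without KD replicate 1 (0.14, adjusted p = 0.0529) or without KI replicate 2 (0.25, adjusted p = 0.136). It was also called higher with the replicate block (0.66, adjusted p = 0.0312) and in its 17 genes of at least 20 CPM, a limit chosen after seeing the data (0.89, adjusted p = 7.2e-05). All of these calls used the preset correlation, and with all 4 libraries the list had adjusted p = 0.923 with an estimated correlation. The dendritic cell and MHC class II list had a median of -1.59 (adjusted p = 0.881) with Zbtb46 at -2.80 ± 0.82, Tcf4 at 0.77 ± 0.35 and H2-DMa at 1.15 ± 0.59. Zbtb46 lay at -1.51 without KI replicate 1 and -3.36 without KI replicate 2. In this list H2-DMa and Tcf4 lay at 2.39 and 1.30 without KI replicate 1, and at 0.62 and 0.57 without KI replicate 2. The list covered 15 genes with all 4 libraries. Its median was 1.30 over 15 genes without KI replicate 1, the library with the high receptor counts. Over 19 genes it was -2.52 without KI replicate 2. With all 4 libraries it had adjusted p = 0.956 with an estimated correlation. The mast cell, basophil and eosinophil list had a median of 0.20 over 12 genes (adjusted p = 0.187). It had 0.67 over 14 genes without KI replicate 1, and 0.43 over 15 without KD replicate 2. Its median was -0.08 without KD replicate 1, and with all 4 libraries it had adjusted p = 0.923 with an estimated correlation. Within it the eosinophil granule genes Prg2 and Prg3 lay higher in KD (4.29 ± 1.09 and 2.87 ± 1.08, or 2.35 and 1.62 without KD replicate 1), and Il1rl1, the interleukin 33 receptor, lower (-3.07 ± 0.57), the 1 member that passed when adjusted over the list alone.

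Erythroid genes were lower in KD throughout the list. All 25 measured members had a negative fold change, and 24 lay lower in both KD libraries than in both KI libraries. The median member had 29.5 and 43.3 CPM in the KI mice, 4.39 CPM in KD replicate 1 and 0.346 CPM in KD replicate 2. The red cell membrane genes Ermap and Rhd had log2 fold changes of -3.60 ± 0.87 and -3.67 ± 0.90 (SE), and the adult beta globin Hbb-bs, named after its values were seen, lay at 127 and 132 CPM against 16.6 and 0.518. Tfrc, the transferrin receptor, which dividing cells of other lineages also use, had a smaller difference of -1.32 ± 0.41 (-0.81 without KD replicate 2). The list median was -3.47, with adjusted p = 2.0e-15 by camera with the preset correlation and adjusted p = 0.889 with an estimated correlation. No member passed over all genes tested, and 17 passed, all lower, when adjusted over the list alone. The estimated correlation of the list was 0.768, against the preset 0.01. Without each library in turn the median stayed negative, from -6.08 without KD replicate 1 to -2.59 without KD replicate 2. Alignments that were not unique were counted for no gene, so near-identical copies such as the alpha globin pair Hba-a1 and Hba-a2 may have lost counts. Their single values are uncertain, as are those of the similar Hbb-bs, Hbb-bt and Hbb-y and of the Schlafen genes. The megakaryocyte and platelet list had a median of -0.87 (adjusted p = 0.186), with Gp1bb at -2.83 ± 0.86, Gp5 at -2.76 ± 0.94 and Rab27b at -1.98 ± 1.07, all below 12 CPM in every library. Rab27b, whose groups overlap, lay at 0.22 without KI replicate 1. The megakaryocyte median covered 10 genes with all 4 libraries. It was -1.64 over 14 genes without KD replicate 1, but 0.09 over 12 for this list without KI replicate 1. With all 4 libraries it had adjusted p = 0.923 with an estimated correlation.

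T cell genes were low in all 4 libraries, and the median member was highest in KI replicate 1, the library whose silent receptor genes summed to 832 CPM. Of 23 measured T cell genes 22 had a negative fold change, with a median of -1.56, and the median member had 6.26 CPM in KI replicate 1, 2.14 in KI replicate 2, 1.34 in KD replicate 1 and 1.73 in KD replicate 2. Cd3e, a chain of the T cell receptor complex, went beyond this, at 6.26 and 37.3 CPM in KI against 1.34 and 0.518 in KD (log2 -4.52 ± 1.04, SE; -2.59 without KI replicate 2). Themis and Cd6 lay at -2.19 ± 0.65 and -2.41 ± 0.82. All 8 measured NK and innate lymphoid genes were negative, with a median of -1.55, led by Il18rap (-1.68 ± 0.32) with Eomes and Ccl5 at -2.23 ± 0.91 and -1.95 ± 0.87 (-0.92 and -0.94 without KI replicate 1). Both lists were lower by camera with the preset correlation (T cell adjusted p = 4.8e-05, NK adjusted p = 0.0214). They were not called with an estimated one: T cell adjusted p = 0.923 with an estimated correlation of 0.379, NK adjusted p = 0.889 with an estimated correlation of 0.0555. In edgeR with all 4 libraries Il18rap was the 1 member of these 2 lists that passed when adjusted over the list alone, and 0 passed over all genes tested. DESeq2 called Cd3e (adjusted p = 0.00089) and Il18rap (adjusted p = 0.0078) over all genes. The T cell call ended without KI replicate 1 (median 0.19, adjusted p = 0.309). The NK call ended without KI replicate 1 (-0.32 over 10 genes), without KD replicate 1 (-1.66 over 14) and without KD replicate 2 (-1.59 over 13). The B cell list had a median of -0.96 (adjusted p = 0.559), with Ighm at 0.80 ± 0.35, Ebf1 at -2.30 ± 1.25 and Cd72 at -1.58 ± 0.91. Ighm lay at 0.50 without KD replicate 2, and Ebf1 and Cd72 at 0.81 and -0.16 without KI replicate 1. The B cell median covered 11 genes with all 4 libraries, and other members entered the leave-one-out fits. It was -2.41 over 16 genes without KI replicate 2 and -2.42 over 18 without KD replicate 2, but 0.42 over 12 without KI replicate 1. The stroma and endothelium list had a median of -1.58 (adjusted p = 0.395), with Emcn at -2.72 ± 1.04, Col1a1 at -1.84 ± 0.80 and Col3a1 at -1.79 ± 0.95 (the collagens -1.17 and -0.60 without KI replicate 1). The stroma median covered 13 genes with all 4 libraries. It was -2.30 over 20 genes without KI replicate 2, but 0.47 over 13 without KI replicate 1. The B cell and stroma lists each had, with all 4 libraries, adjusted p = 0.923 with an estimated correlation.

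**Figure D3:**
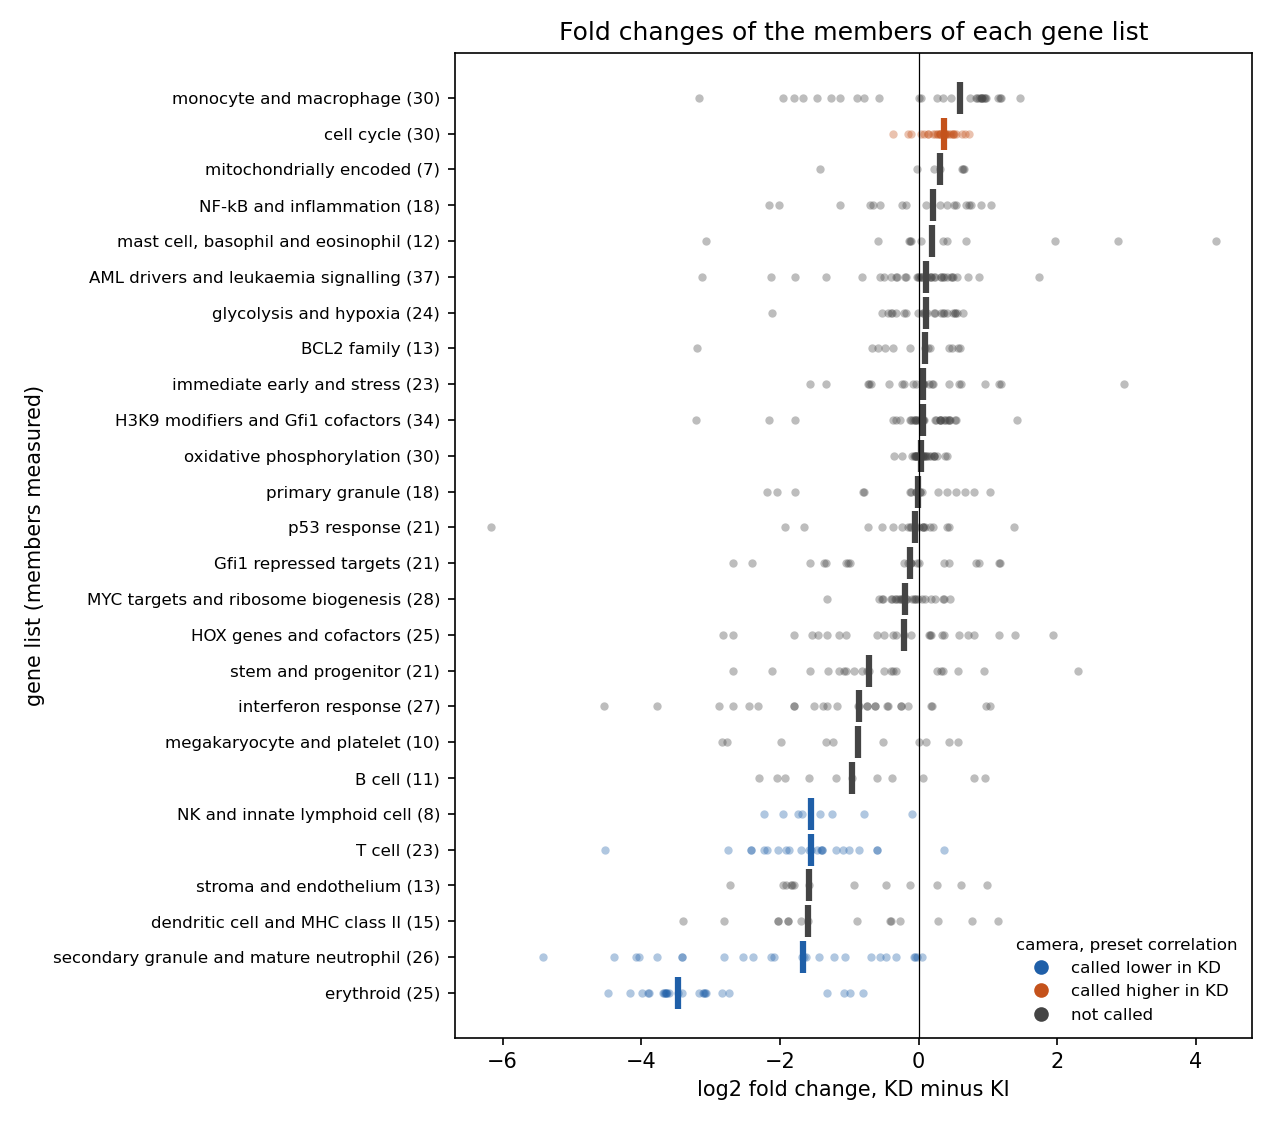
Each dot is the log2 fold change (KD minus KI) of 1 measured member of a gene list, and each vertical bar is the list's median; the number of members measured is in parentheses. Colour marks the camera call with the preset correlation: 4 lists called lower (blue, medians from -3.47 for erythroid to -1.55 for NK), 1 called higher (orange, cell cycle, 0.36) and the rest not called (grey).

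Genes that Gfi1 is known to repress were not called as a group. Of 21 measured members of that list 7 had a positive and 14 a negative fold change, with a median of -0.12 (adjusted p = 0.750), which ran from -0.35 without KI replicate 2 to 0.18 without KI replicate 1. The 8 members in no other list had a median of -0.60 (adjusted p = 0.161). Ets1, a transcription factor of lymphoid and endothelial cells, was lower in KD at 113 and 89.0 CPM in KI against 24.8 and 13.2 in KD (log2 -2.41 ± 0.41, SE) and was the 1 member that passed when adjusted over the list alone. Irf8, a regulator of monocyte fate, lay at 0.87 ± 0.33. Among HOX genes and cofactors Hoxc6 and Hoxc4 were higher in KD by 1.94 ± 0.42 and 1.39 ± 0.50. Hoxc4 lay at 1.06 without KI replicate 1 and 2.28 without KI replicate 2. Hoxc8, a member of the same cluster named after its values were seen, lay at -1.45 ± 1.14. In edgeR with all 4 libraries none passed over all genes, nor any member of this list adjusted over the list alone. DESeq2 called Hoxc6 (adjusted p = 0.032). The list had a median of -0.21 (adjusted p = 0.467) and was called higher without KI replicate 1 (1.00, adjusted p = 0.0057), but its median was -0.73 without KI replicate 2 (adjusted p = 0.539). With all 4 libraries it had adjusted p = 0.923 with an estimated correlation. The stem and progenitor list had a median of -0.71 (adjusted p = 0.618; 0.27 without KI replicate 1), and its 3 members with the lowest p went both ways. Cd34, a surface marker of progenitors, lay at 32.5 and 6.41 CPM in KI against 68.4 and 120 CPM in KD (2.30 ± 0.78). It lay at 3.99 without KI replicate 1 and 1.61 without KI replicate 2. Kit, the stem cell factor receptor, and Erg lay at -0.82 ± 0.29 and -1.04 ± 0.37 (Erg -0.69 without KD replicate 1). In the list of AML drivers and leukaemia signalling genes, with a median of 0.11 (adjusted p = 0.187), Trib1 lay at -2.12 ± 0.56 and Il3ra, the interleukin 3 receptor, at 1.74 ± 0.74. Il3ra rested on KD replicate 2 (10.4 and 9.37 CPM against 11.7 and 54.6) and lay at 0.32 without it. The list of H3K9 modifiers and Gfi1 cofactors had a median of 0.06 (adjusted p = 0.186), with Hdac11 at -3.21 ± 1.02 and Rcor2 at -2.16 ± 0.87, both below 7 CPM in every library. Hdac9 lay at 1.42 ± 0.66 (0.56 without KD replicate 2), and Hdac11 and Rcor2 at -1.91 and -1.37 without KI replicate 1. The AML list was called higher without KI replicate 2 (0.28, adjusted p = 0.0335) and without KD replicate 2 (0.19, adjusted p = 0.0171), and so was the H3K9 list (0.23, adjusted p = 0.0124, and 0.11, adjusted p = 0.0254). In the fit of all 4 libraries both had adjusted p = 0.889 with an estimated correlation. Neither was called without KI replicate 1 (0.21, adjusted p = 0.126, and 0.15, adjusted p = 0.280) or without KD replicate 1 (0.10, adjusted p = 0.0762, and 0.21, adjusted p = 0.0594). The median of the Gfi1 target list was 0.26 and that of the HOX list 0.14 with library size only, and that of the H3K9 list -0.0064 with upper quartile scaling. The means of the HOX, AML and H3K9 lists were -0.33, -0.09 and -0.05, while camera's direction for these 3 lists was higher in KD.

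Proliferation genes had small positive fold changes, but most did not separate the genotypes. In the cell cycle list 27 of 30 members had a positive fold change. Only 7 lay higher in both KD libraries than in both KI libraries, and 1 lay lower in both. The median member had 53.2 and 108 CPM in the KI mice and 86.4 and 109 CPM in the KD mice. The median log2 fold change was 0.36, and 0.88 without KI replicate 2. Bub1, a mitotic checkpoint kinase, lay at 0.72 ± 0.28, Mki67, the Ki-67 antigen, at 703 and 853 CPM against 1227 and 1184 (0.63 ± 0.34, SE), and Cenpe at 0.68 ± 0.40 (0.39 without KI replicate 1). Camera called the list higher with the preset correlation (adjusted p = 0.000244) and not otherwise (adjusted p = 0.923 with an estimated correlation, which was 0.902). In edgeR 0 members passed over all genes or adjusted over the list alone. The call ended without KI replicate 1 (median 0.08, adjusted p = 0.537), and the median shrank to 0.06 without KD replicate 2 (adjusted p = 0.0088). The p53 response list had a median of -0.05 (adjusted p = 0.881), with Trp53inp1 at -1.65 ± 0.33 Dcxr at 1.38 ± 0.62, and Perp, an effector of p53-dependent death, at 4.17 and 43.2 CPM in KI against 0.142 and 0.518 in KD (-6.17 ± 1.38, or -3.58 without KI replicate 2). The BCL2 family had a median of 0.09 (adjusted p = 0.666), with Hrk at -3.19 ± 1.13, Bid at 0.60 ± 0.31 and Bcl2l1 at -0.58 ± 0.35. Hrk lay at -1.15 without KI replicate 1 and Bcl2l1 at -0.36 without KD replicate 2. In leave-one-out fits the p53 median ran from -0.21 to 0.01 and the BCL2 median from -0.11 to 0.29. With library size only the p53 median was 0.33, with upper quartile scaling the BCL2 median was -0.02, and the mean of the BCL2 list was -0.23 beside a test direction of higher in KD.

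Metabolic and signalling lists had small medians, and their calls rested on the setting. Vegfa, the vascular growth factor, stood out in the glycolysis and hypoxia list at 32.5 and 45.9 CPM in KI against 9.84 and 8.21 in KD (log2 -2.12 ± 0.36, SE). It was the 1 member that passed when adjusted over the list alone. P4ha1 and Hk2 lay at 0.56 ± 0.32 and 0.49 ± 0.30. They lay at 0.90 and 0.93 without KI replicate 1, and at 0.47 and 0.35 without KI replicate 2. The list had a median of 0.11 (adjusted p = 0.258) and was called higher without KI replicate 2 (0.45, adjusted p = 0.0052) and without KD replicate 1 (0.44, adjusted p = 0.0170). Its median was -0.03 without KD replicate 2 and 0.05 without KI replicate 1, and with all 4 libraries it had adjusted p = 0.923 with an estimated correlation. Oxidative phosphorylation, with Cycs, Sdhb and Ndufb3 at 0.41 ± 0.41, 0.39 ± 0.42 and -0.35 ± 0.62, all with groups that overlap, had a median of 0.04 (adjusted p = 0.0903; -0.0025 with upper quartile scaling). It was called higher without KI replicate 2 (0.93, adjusted p = 1.1e-08) and without KD replicate 1 (0.35, adjusted p = 0.000385). Its median was -0.31 without KI replicate 1 (adjusted p = 0.0525) and -0.18 without KD replicate 2 (adjusted p = 0.0907). The call of higher was made with the replicate block (0.16, adjusted p = 0.0312) and with satellite loci left out, chosen after seeing the data (0.14, adjusted p = 0.0423). With all 4 libraries this list had adjusted p = 0.923 with an estimated correlation, which was 0.987. Without KI replicate 1 Cycs and Sdhb lay at 0.16 and 0.12, and without KI replicate 2 Ndufb3 lay at 0.92. MYC targets and ribosome biogenesis, with Wdr43 and Bop1 at -0.52 ± 0.42 and 0.46 ± 0.41 beside Tfrc (Wdr43 0.19 without KI replicate 2, Bop1 0.17 without KI replicate 1), had a median of -0.20 (adjusted p = 0.671). Its mean was -0.17, its test direction higher in KD and its median 0.27 under library size only. This list was called lower without KI replicate 1 (-0.47, adjusted p = 0.0038), and higher without KI replicate 2 (0.57, adjusted p = 1.3e-05) and without KD replicate 1 (0.05, adjusted p = 0.0445). Its estimated correlation was 0.867, and with all 4 libraries it had adjusted p = 0.951 with an estimated correlation. Without KD replicate 2 it was not called (-0.32, adjusted p = 0.328). The mitochondrially encoded genes had a median of 0.31 (adjusted p = 0.444), with mt-Nd6, mt-Cytb and mt-Nd4 at -1.43 ± 0.55, 0.63 ± 0.49 and 0.65 ± 0.55, and were called higher without KD replicate 2 (1.04, adjusted p = 0.0104). Their median was -0.14 without KD replicate 1, and with all 4 libraries they had adjusted p = 0.923 with an estimated correlation. Without KI replicate 1 mt-Nd6 lay at -0.32, and without KD replicate 1 mt-Cytb and mt-Nd4 lay at 0.22 and -0.071. The NF-kB and inflammation list had a median of 0.21 (adjusted p = 0.228), a mean of -0.09 and a test direction of higher in KD, with Traf1 at -2.15 ± 0.92 and Nfkbia, the inhibitor of NF-kB, at -1.13 ± 0.60 beside Nfkb1. Traf1 lay at -0.58 without KI replicate 1, and Nfkbia, whose groups overlap, at -0.11 without KI replicate 2. It was called higher without KI replicate 1 (1.101, adjusted p = 0.0049) and without KD replicate 2 (0.28, adjusted p = 0.0254). Its median was -0.16 without KI replicate 2 and -0.15 without KD replicate 1. The immediate early and stress list had a median of 0.07 (adjusted p = 0.634), with Fos at 1.16 ± 0.59 and Egr2 at -1.57 ± 0.90 beside Klf4 (Fos 0.22 without KD replicate 1, Egr2 -0.60 without KI replicate 1), and was called higher without KD replicate 2 (0.58, adjusted p = 5.9e-05), but its median was -0.46 without KD replicate 1. The NF-kB and immediate early lists each had, with all 4 libraries, adjusted p = 0.923 with an estimated correlation.

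Of the 27 measured interferon genes 25 were highest in KI replicate 1, the library with the high receptor counts. The exceptions, Gbp2 and Gbp3, named after their values were seen, were highest in KD. Whether the interferon levels and the receptor counts of that library are linked was not tested. The interferon response list had a median of -0.86 (adjusted p = 0.395), with the antiviral genes Rsad2, Oasl2 and Ifit2 at -3.77 ± 1.21, -4.54 ± 1.49 and -1.38 ± 0.48 (-1.03, -0.74 and -0.78 without KI replicate 1). Rsad2 and Oasl2 were high in KI replicate 1 alone, at 51.5 and 35.3 CPM against at most 4.63 in the other 3 libraries, and the list's median was 0.78 without that library (adjusted p = 0.0057, higher in KD) and -1.66 without KI replicate 2 (adjusted p = 0.000481, lower in KD). It was also called lower without KD replicate 1 (-1.02, adjusted p = 0.0146) and not without KD replicate 2 (-0.56, adjusted p = 0.989). Its estimated correlation was 0.786, and with all 4 libraries it had adjusted p = 0.923 with an estimated correlation.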

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

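Gfi1 was lower in KD in every setting run, and passed the threshold in DESeq2 (-3.76), without the low-count filter (-3.78) and in some leave-one-out fits, whose values ran from -5.73 to -2.96. Genes called higher in KD came to 29 without the filter, 5 in DESeq2 and 2 to 284 in leave-one-out fits, and genes called lower to 140, 137 and 9 to 3846, with 7 for the replicate block (Itgb2l, Slfn4, Ly6g, Retnlg, Ltf, Camp and Hbb-y; of these Ly6g, Retnlg and Ltf were named after their values were seen). The count was 0 in both directions with RLE, upper quartile and library size only scaling, at least 5 CPM, the fold threshold, limma-voom, and, chosen after seeing the data, without satellite loci, with a robust prior and without sex-linked genes, where edgeR and limma-voom had 562 to 1898 genes at an unadjusted p under 0.05. Without KI replicate 1 and without KI replicate 2, 80 called genes were shared of 316 and 4130. Without KI replicate 2 the lone KI library is KI replicate 1, the library with the high receptor counts. Leave-one-out fits rerun the filter, so a gene can enter through 1 library alone, and tested 14164 to 16983 genes against 13822. These fits have fewer samples and assume that the lone mouse varies like the other genotype. They also leave 1 genotype with 1 replicate number, so differences that go with replicate number, as in sex-linked genes, enter the comparison. Xist, a sex-linked gene, lay at -9.86 without KD replicate 2, against 0.08 with all 4 libraries. For the other settings the cause was not tested. In the labels only the replicate numbers could pair the mice. They also go with the levels of sex-linked genes in both genotypes, so the replicate block also adjusts for what goes with those levels. The correlation across genes of the replicate differences was 0.249 between genotypes (0.504 in genes of at least 20 CPM). Of 93 other named genes, 29 passed in DESeq2, 24 without the filter and 4 with the replicate block, and none of the 93 changed direction or side with RLE, upper quartile scaling or limma-voom. Library size only moved the median log2 fold change of all genes from -0.06 to 0.37 and reversed Ndufb3 (0.14; leave-one-out -0.85 to 0.92), and the missing filter moved that median to -0.76. Of the lists, 1 was called higher and 4 lower; with an estimated correlation and with fry these became 0 and 0. Lists called higher were 3 with the replicate block (cell cycle, monocyte, oxidative phosphorylation), 2 without satellite loci (cell cycle, oxidative phosphorylation), 2 at 20 CPM or more (cell cycle, monocyte) and 4 to 8 in leave-one-out fits, and lists called lower 3 to 8 in leave-one-out fits. The median took both signs in leave-one-out fits for 19 of the 26 lists, some of which held other members than with all 4 libraries. Lists called there against the direction of the test with all 4 libraries were MYC (-0.47 to 0.57), dendritic (-2.52 to 1.30) and interferon (-1.66 to 0.78), and named genes whose sign changed were Ebf1 (-3.14 to 0.81), Rab27b (-2.72 to 0.22), Wdr43 (-0.82 to 0.19) and mt-Nd4 (-0.071 to 1.35). The T cell list had no member at 20 CPM or more and gives no value there. Not run, since no chromatin value could be matched to a library, were the alternatives for H3K9ac at promoters and for H3K9ac against RNA: window, control, pseudocount, centring, filter, start site, pairing, replicates, RNA genes and scaling.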

Other observations

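Tests of background from silent receptor genes, of satellite DNA background and of weaker poly(A) selection were chosen only after the result was seen; the other tests were written before their values were computed. Some embryonic globin genes were higher in KI: besides Hbb-y, Hba-x, an embryonic alpha-like globin, had 26 and 37 counts in KI and 2 and 2 in KD (log2 -4.94 ± 0.85, SE), while Hbb-bh1, another, had 1 and 2 counts in KI, was listed at 0 in KD and was not tested. In a list of fetal genes chosen after the data were seen, Lin28a, an RNA-binding protein of early development, lay at 27.1 and 37.8 CPM against 8.92 and 10.2 (-1.77 ± 0.36), while Lin28b and Igf2bp3 lay the other way (1.18 ± 0.67 and 1.29 ± 1.12). None of these genes passes over all genes in edgeR with genotype as the only term and all 4 libraries; Hbb-y passes with the replicate block (adjusted p = 0.0015). In DESeq2 with the same libraries Hbb-y, Hba-x and Lin28a pass (adjusted p = 1.3e-17, adjusted p = 0.0061 and adjusted p = 0.0366).

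Sex-linked genes differed by replicate number in both genotypes. Xist, the RNA of the inactive X chromosome, lay at 785 and 846 CPM in replicate 2 of KI and KD and had 56 and 6 counts in replicate 1. The Y-linked genes Uty, Kdm5d and Eif2s3y lay at 29.9, 48.0 and 58.0 CPM in KD replicate 1 and 46.2, 48.2 and 83.7 in KI replicate 1. In replicate 2 of both genotypes each lay at 0.712 CPM or less. Ddx3y, also Y-linked, had 18 counts in KD replicate 1 (1.27 CPM) against 77.5 CPM in KI replicate 1. Apart from that value, replicate 1 of each genotype had the pattern of male cells and replicate 2 that of female cells. The main fit has no term for this. The split of the 4 libraries by replicate number had 1528 genes at an unadjusted p under 0.05, the split by genotype 1331 and the remaining split 132, with 0 genes past the adjusted threshold in edgeR for each; 3 splits are too few for a test.

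KI replicate 1 had the fewest gene counts and the most genes with a count, 27355. Depth was argued against: thinned to the same total, it kept 1.36 times the genes of the next library. Silent receptor genes were 5.02 times those of the next library, so that background from genomic DNA or unspliced RNA may add to its low genes. The T cell list, with a median of 0.19 without this library, could owe its call in part to that background. Of its 23 measured members 17 were highest in KI replicate 1 and 5 in KI replicate 2, among them Cd3e (6.26 and 37.3 CPM in KI). The secondary granule and erythroid lists, at -1.44 and -3.29 without it, could not be explained by it.

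Satellite loci were higher in both KI libraries, with a median log2 fold change of -1.43. DNA background stays open: the satellite ratio to KD was 2.00 times the receptor ratio in KI replicate 2 (3.18 and 1.59), but KI replicate 1 went the other way (2.55 and 7.27). Weaker poly(A) selection was argued against only weakly: 4 RNAs without a poly(A) tail had a median of 0.157 (0.08 to 0.44), with standard errors of 0.42 to 0.65. In the KI libraries Terc lay at 8.12 and 33.1 CPM, Rpph1 at 1425 and 4546, Rmrp at 632 and 1267, and Rn7sk at 3084 and 3702. Alignments that were not unique, per other gene count, were 3.32 times higher in KI (67.2 and 37.3 against 16.2 and 15.2), so repeat-derived reads as a class may be higher in KI, and which locus they came from cannot be told.

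Fewer mature neutrophils in KD would lower their genes by a common amount only if no other cells in the sample expressed them. The interquartile range of 10 neutrophil genes was 3.95 times their median standard error, with values from -4.07 for Retnlg to -0.06 for Mmp8. Since expression in other cells was not measured, this spread cannot decide whether a smaller share of neutrophils alone lowered these genes. A change in the maturation programme itself may also contribute, which bulk RNA cannot separate from a mixed cell population. For the erythroid list, no test of cell share was run.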
